A study of Homo sapiens with 5 samples.

How the data were processed

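GFP-SAS cells, a human tongue squamous cell carcinoma line, were treated for 24 h in 5 groups: DMSO, 100 nM MLN8237, a non-targeting siRNA (siNT), and 10 nM siAURKA-1 or siAURKA-2. Groups follow the treatment named in the labels, with 1 array per group. The dose of siNT was not used here because the labels can be read in more than 1 way. Per the labels, total RNA was extracted with ISOGEN and 10 ng was labelled with biotin by a 3' in vitro transcription kit for the Affymetrix GeneAtlas system. Probes of such arrays lie toward the 3' end of transcripts, and labelling from little RNA involves amplification, which can distort the relative levels of individual transcripts.

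The deposited values are taken as log2 signal. Robust multi-array average (RMA), which corrects background, normalizes quantiles and summarises probes by median polish, is named in the submitters' processing notes. The software, its version and the log base are not given in the sources used here. In the table of 49386 probe sets, the median over the 5 arrays was exactly 0 for 49386 of them, so the authors' values had been centred per probe set, a step also not given in the sources used here. Centring cancels in a difference between arrays but leaves no expression level, so genes near background could not be filtered out. The value 0 occurred on 2 or more arrays in 52.1% of probe sets, a tie that median polish can produce. For arrays, the number of arrays limits precision, and here it allows no estimate of error.

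Of the probe sets, 93 were controls, 45259 named 1 gene symbol, 1327 named several and 2713 had no listed gene. Symbols were matched by Entrez number to a current gene table. The value of a gene was the median of its probe sets, giving 18239 genes, 6416 of them with 1 probe set. Among the 266 genes that the rule below names, list members included, 174 had several probe sets, and 45 to 66 per comparison had a probe set that did not share the direction of the median.

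With 1 array per group no test could be run and no p-value is given. Comparisons were siAURKA-1 minus siNT, siAURKA-2 minus siNT, MLN8237 minus DMSO and siNT minus DMSO, the last as the background of the others, although it includes any effect of transfection against vehicle. Genes were counted at 2-fold, with 1.5-fold and 3-fold as alternatives. Overlaps were set beside the number expected of independent lists and beside 1000 simulations of unchanged groups sharing 1 control array, in which each array's deviation was drawn from the siNT minus DMSO differences of all genes, divided by the square root of 2. Each deviation was given a random sign, so these simulations hold no skew between higher and lower readings. The planned dependence of this spread on signal could not be kept without expression levels. A further simulation, added after the data were seen, drew deviations among genes of like standard deviation over the arrays (20 bins). Simulated correlations and covariances with the mean of both siRNAs were added in the same way as those of single arrays, also after the data were seen, and all simulated arrays have the same spread. For 22 gene lists (500 entries, 35 of them without a gene in the table) the median difference was given with its percentile among 10000 random lists of the same size. A median counted as outside the random lists below percentile 2.5 or above 97.5. The percentile describes these arrays and is not a p-value, since genes of a list are co-regulated. The lists covered mitosis, DNA replication, Aurora cofactors, p53 targets, the BCL2 family, interferon-stimulated, NF-kB and cytokine, keratinocyte differentiation, basal epithelial, mesenchymal, stress response, cholesterol synthesis, hypoxia, heat shock, NRF2 target, immediate early, histone, ribosome biogenesis and ribosomal protein genes, and fibroblast, leukocyte and endothelial markers.

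Groups, comparisons, gene lists, thresholds and the rule for naming genes were fixed before the data were examined. The rule took 8 cell cycle and p53 genes in every comparison, the 12 highest and 12 lowest genes by the smaller difference of the siRNAs and by the MLN8237 difference, the 10 highest and lowest by the smallest of all 3 differences, 5 each way between controls, 6 each way between siRNAs, 5 each way where siRNAs and MLN8237 were opposite, and up to 4 genes per list. Other genes are stated as chosen after their values were seen. Because the values carry no expression level, 3 planned choices could not be used. A filter on low genes was dropped, the probe set of highest mean was replaced by the median of probe sets, and random lists were matched on the gene's standard deviation over the 5 arrays (20 bins) instead of on mean expression. The first 2 replacements had been planned as alternatives, and the last was chosen after the values were seen.

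Alternatives planned before the data were examined were other thresholds, each array centred on its median, the other control array, a different control for each siRNA, and random lists without matching. Those added later were the probe set with the widest range, probe sets without an s or x suffix (which marks probes shared between transcripts or genes), each array centred on its mean, the mean of both controls, matching on the number of probe sets, and the other control array for named genes.

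The procedure was tested on simulated data. Of 50 genes simulated as 3-fold different with both siRNAs, 50 were counted at 2-fold, and of 18039 simulated as unchanged, 6 were counted. Here deviations were drawn separately for each probe set, so the median over a gene's probe sets reduced them. Simulated unchanged groups with deviations drawn per gene gave more, 6.59 higher and 6.83 lower genes on average. A list shifted by -0.30 was recovered at -0.30, and 4 of 87 unshifted list medians lay outside the random lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Probe sets that name several genes or none were left out of the gene counts, and siRNA sequences were not used here.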

Results

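Gene expression was profiled in GFP-SAS cells, a human squamous cell carcinoma line from the tongue that carries green fluorescent protein. Cells were exposed for 24 h to DMSO vehicle, to 100 nM MLN8237 (alisertib, an inhibitor selective for Aurora kinase A), to a non-targeting siRNA (siNT), or to 10 nM of either of 2 siRNAs against AURKA (siAURKA-1 and siAURKA-2). AURKA encodes Aurora kinase A, a serine/threonine kinase of centrosomes and the mitotic spindle. Each of the 5 groups was measured on 1 Affymetrix GeneAtlas array, which gave values for 18239 genes. No difference reported here has a replicate check, and the number of arrays limits the precision of every value. The deposited values were centred per probe set, so they compare arrays and do not rank genes by abundance. Differences are given on the log2 scale, taking the values as log2, and gene counts use a fixed size of at least 2-fold.

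The knockdown was examined at the level of its target. AURKA, read by a single probe set, was 10.3-fold lower with siAURKA-1 than with siNT (log2 difference -3.36) and 6.24-fold lower with siAURKA-2 (-2.64). This left 9.71% and 16.0% of the siNT value. With MLN8237, which acts on the kinase protein, AURKA mRNA was 1.40-fold higher than with DMSO (0.49). Between the 2 controls it differed by -0.15 (siNT minus DMSO). AURKB, encoding the related kinase of the chromosomal passenger complex, was lower with siAURKA-1 (-0.95) and with siAURKA-2 (-0.39), and near DMSO with MLN8237 (-0.07). PLK1, a mitotic kinase activated through Aurora A, differed little in any of these comparisons (-0.04, -0.10 and 0.01), although its 3 probe sets did not share a direction. TPX2, the spindle protein that activates Aurora A, gave -0.38 with siAURKA-1, 0.07 with siAURKA-2 and 0.16 with MLN8237. The 12 measured Aurora kinases and cofactors, AURKA itself left out, had medians of -0.15 with siAURKA-1, 0.01 with siAURKA-2 and 0.04 with MLN8237, all within the middle 95% of matched random lists. Against random lists without matching, the siAURKA-1 median lay outside (percentile 0.46).

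**Figure D1:**
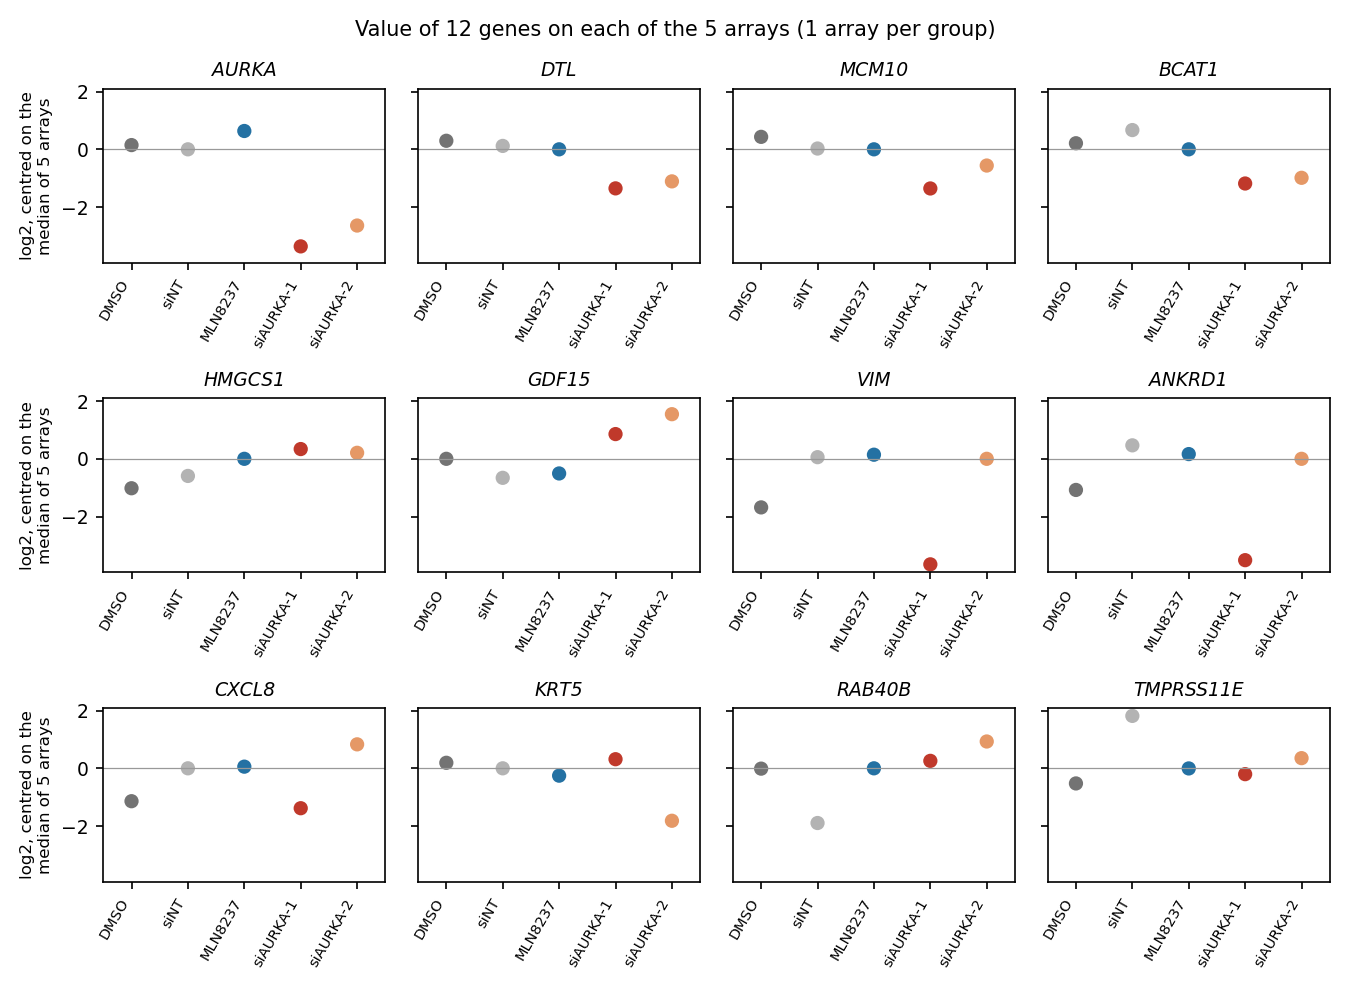
Value of 12 genes on each of the 5 arrays (1 point per array, log2, each gene centred on its median over the arrays). AURKA lies at -3.36 and -2.64 on the siRNA arrays, while RAB40B at -1.90 and TMPRSS11E at 1.82 stand apart on the siNT array.

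Genes that differed with both siRNAs were sought to separate effects shared by the reagents from those of either alone. Among genes lower than siNT with both were DTL, the substrate receptor of a CUL4 ubiquitin ligase acting in DNA replication (-1.47 with siAURKA-1 and -1.23 with siAURKA-2), BCAT1, the cytosolic branched-chain aminotransferase (-1.85 and -1.65), and the imprinted gene MEST (-1.70 and -1.43). MSRB3, a methionine sulfoxide reductase (-1.19 and -1.20), the small nucleolar RNA gene SNORD17 (-1.47 and -1.19) and KLHL15, an adaptor of CUL3 ubiquitin ligases (-1.24 and -1.75), were also lower. Genes higher with both included GDF15, a stress-responsive cytokine of the TGF-beta superfamily (1.52 and 2.21), IFNE, encoding interferon epsilon (1.76 and 1.43), the sialyltransferase gene ST6GALNAC2 (1.26 and 1.39), the translational regulator CPEB4 (1.44 and 1.26) and GULP1, an adaptor of engulfment receptors (2.30 and 1.18). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was higher by 1.05 and 0.75. MDM2, like CDKN1A a target of p53, gave 0.24 and 0.01.

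In number, 358 genes differed at least 2-fold between siAURKA-1 and siNT (107 higher, 251 lower) and 230 between siAURKA-2 and siNT (71 higher, 159 lower). Of these, 15 were higher and 35 lower with both siRNAs. The excess of lower genes with siAURKA-2 and with both depends on the siNT array: against DMSO siAURKA-2 gave 132 higher and 102 lower, both siRNAs 23 and 19, and siAURKA-1 134 and 189. Independent lists of these sizes would share 0.417 and 2.19 genes, and simulated unchanged groups compared with 1 shared control array shared 6.59 and 6.83 on average, with maxima of 13 and 14. When the simulated deviations were drawn among genes of like spread over the arrays, the maxima were 15 and 15, so that the 15 shared higher genes reached but did not exceed the simulated range, while the 35 lower genes did. Because both comparisons use the siNT array, each gene was also set against the other arrays. ANKRD22, IFNE and ST6GALNAC2 were at least 2-fold higher on both siRNA arrays than on both the DMSO and the MLN8237 array. AURKA, DTL, APLN (encoding apelin) and FABP5 (a fatty acid binding protein) were at least 2-fold lower in the same way. ANKRD22, APLN and FABP5 are named here after their values were seen. Against DMSO, 4 of the 15 and 8 of the 35 stayed at least 2-fold apart with both siRNAs. Several others depended on siNT. With siAURKA-1, KLHL15 was -0.53 and GDF15 0.86 against DMSO. RAB40B, a small GTPase gene, was 2.16 and 2.83 above siNT but 0.27 and 0.94 above DMSO, and the myosin light chain gene MYL12B was 1.46 and 1.58 above siNT but 0.17 and 0.29 above DMSO. C2orf15, ZNF428 and PI4K2A showed the same kind of difference, with siNT at -1.15, -0.96 and -0.78 relative to DMSO. Among the lower genes, TMPRSS11E, a transmembrane serine protease gene, was below siNT (-2.02 and -1.46) yet above DMSO (0.32 and 0.88). ANGPTL4, a secreted inhibitor of lipoprotein lipase, was below siNT (-1.24 and -1.20) and level with DMSO (-0.01 and 0.04). ALOX5AP, which serves leukotriene synthesis, and the extracellular protease genes PRSS23 and ADAMTS1 lay 1.54, 1.07 and 0.98 higher on the siNT array than on the DMSO array. With siNT as control for siAURKA-1 and DMSO for siAURKA-2, so that no array was shared, 26 genes differed with both (10 higher, 16 lower). The reverse assignment gave 19 (8 higher, 11 lower).

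**Figure D2:**
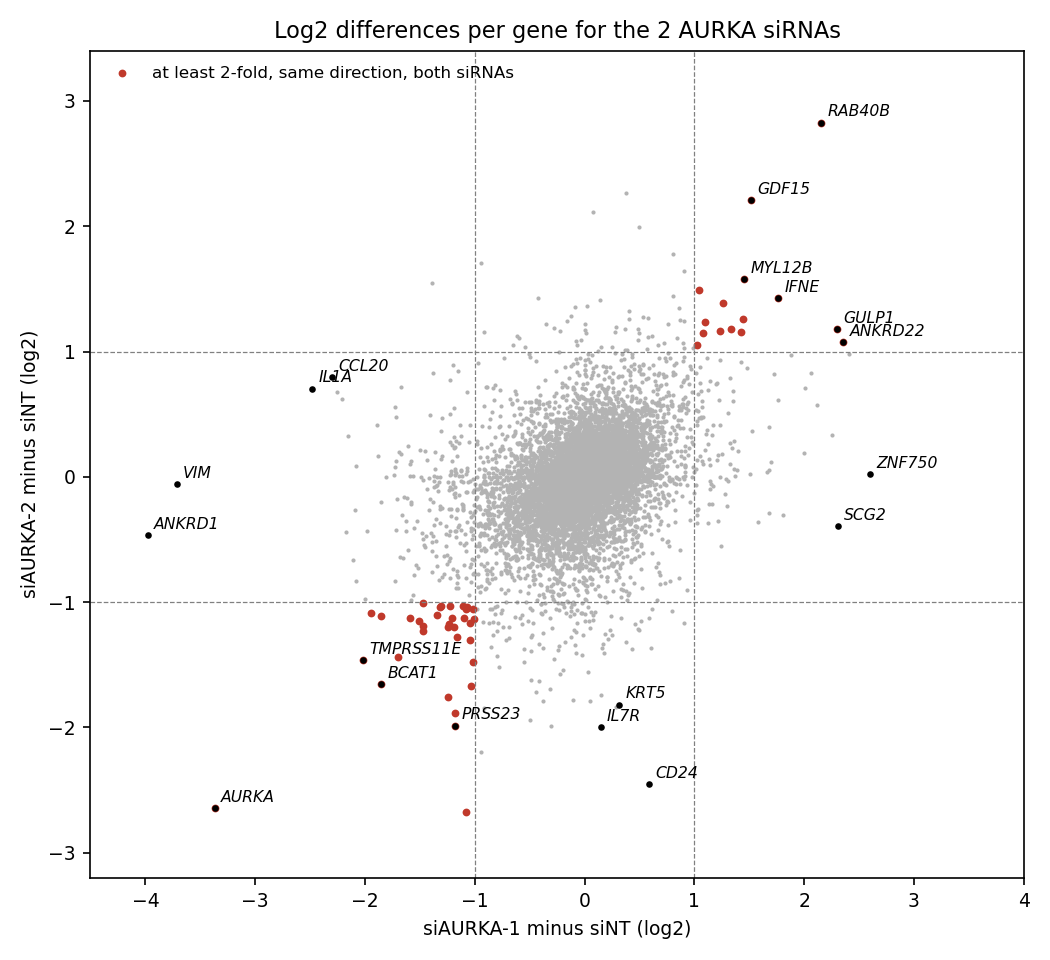
Log2 difference of each of the 18239 genes with siAURKA-1 minus siNT (x axis) and siAURKA-2 minus siNT (y axis), with 1 point per gene. Red points are genes at least 2-fold different in the same direction with both, dashed lines mark 2-fold, and black points are labelled genes, among them AURKA at lower left and VIM and ANKRD1, which lie at -3.72 and -3.98 for siAURKA-1 and at -0.06 and -0.47 for siAURKA-2.

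Across genes, the differences of the siRNAs from siNT had a Pearson r of 0.373 and a Spearman rho of 0.403. Genes are not independent replicates, and sharing a control array alone gave an r of 0.50 in simulated unchanged groups. The covariance was 0.0322 against 0.0191 simulated. With a different control array for each siRNA, r was 0.118 or 0.162.

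DNA replication genes were lower with both siRNAs. The 35 measured S-phase and DNA replication genes had a median of -0.67 with siAURKA-1 (percentile 0.06 among 10000 random lists matched on spread over the arrays), and 24 of them were at least 1.5-fold lower and 0 higher. Examples were POLE2, a subunit of DNA polymerase epsilon (-1.66), and GINS2 and CDC45 of the replicative helicase (-1.27 and -1.26). With siAURKA-2 the median was -0.33 (percentile 2.10), with 11 members at least 1.5-fold lower, among them GINS1 (-0.85), MCM4 (-0.85), MCM2 (-0.81) and the ribonucleotide reductase subunit RRM2 (-0.81). Set against DMSO, both medians were lower still, at -1.01 and -0.68, because the siNT array itself lay below DMSO for this list (median -0.30, percentile 0).

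Mitotic genes differed between the siRNAs. The 35 measured G2/M genes had a median of -0.41 with siAURKA-1 (percentile 0.05), with 12 members at least 1.5-fold lower. TOP2A, encoding DNA topoisomerase II alpha (-1.36), the spindle-associated HMMR (-1.13) and the mitotic cyclin-dependent kinase CDK1 (-0.83) were among them. The median with siAURKA-2 was 0.03 (percentile 83.4) and no member was at least 1.5-fold lower. Here ANLN, a scaffold of the cytokinetic ring (0.61), and PRC1, which bundles the central spindle (0.57), lay above siNT and CCNA2, encoding cyclin A (-0.50), below it. Against DMSO these genes were closer to level with siAURKA-2, at 0.24, 0.10 and -0.35. CCNB1, encoding cyclin B, gave -0.40 and 0.16, and the proliferation marker MKI67 gave -0.70 and 0.03, with 3 of its 6 probe sets in the direction of the median for siAURKA-2. Directly compared, the list lay -0.46 lower with siAURKA-1 than with siAURKA-2 (percentile 0.01), a difference that also has no replicate check.

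Ribosome biogenesis and cholesterol synthesis genes differed from siNT to a similar degree with both siRNAs. The 24 measured ribosome biogenesis genes had medians of -0.25 with siAURKA-1 (percentile 0.14) and -0.25 with siAURKA-2 (percentile 0.03). UTP20, a component of the small subunit processome, was lower with both (-1.16 and -0.85), as were NOLC1 with siAURKA-1 (-0.98) and WDR12 with siAURKA-2 (-0.70). The 26 ribosomal protein genes were nearly level, with medians of 0.04 (percentile 99.2, or 94.1 against DMSO) and -0.01 (percentile 7.82, or 1.57 against DMSO). The 18 cholesterol synthesis genes had medians of 0.25 with either siRNA (percentiles 99.7 and 99.97). HMGCS1, which makes HMG-CoA for the mevalonate pathway, was higher by 0.93 and 0.80, and STARD4, a sterol carrier, by 0.56 and 0.78. The median of the 24 p53 target genes was within the matched random lists for both siRNAs (-0.05 and 0.07). For siAURKA-2 that median lay outside random lists without matching (percentile 98.8). GDF15, CDKN1A and the death receptor gene FAS (1.01) were at least 2-fold higher with siAURKA-1. Against DMSO, GDF15 (0.86) and FAS (0.49) fell short of 2-fold, as siNT lay below DMSO for them (-0.66 and -0.52), while CDKN1A did not. With siAURKA-2, 5 members were at least 1.5-fold higher than siNT, among them GDF15 (2.21) and FAS (0.83), and 2 were at least 1.5-fold lower. CCNG1, encoding cyclin G1, was the member furthest below siNT (-1.78). The 17 BCL2 family genes, regulators of apoptosis, had medians of 0.00 and 0.01.

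The siRNAs also gave different expression of many genes, although both target the same mRNA. In total, 394 genes differed at least 2-fold between their arrays (177 higher and 217 lower with siAURKA-1). VIM, encoding the intermediate filament vimentin, was -3.72 below siNT with siAURKA-1 and -0.06 with siAURKA-2. ANKRD1, an ankyrin repeat cofactor often used as a YAP target, gave -3.98 and -0.47. Because siNT lay above DMSO for both genes, the values against DMSO were -1.97 and 1.68 for VIM and -2.43 and 1.08 for ANKRD1. LCP1, encoding the actin-bundling protein L-plastin, gave -2.25 and 0.68, and SUN3 gave -1.39 and 1.55. In the other direction, ZNF750, a transcription factor of epidermal differentiation, was higher with siAURKA-1 (2.60) and level with siAURKA-2 (0.02). SCG2, encoding secretogranin II, gave 2.31 and -0.39. The surface glycoprotein gene CD24 (0.59 and -2.45), the cytokine receptor gene IL7R (0.15 and -2.00), the basal keratin gene KRT5 (0.32 and -1.82) and DENND6A (0.28 and -1.84) were lower with siAURKA-2. Against DMSO CD24 was 2.25 and -0.79, SCG2 1.44 and -1.26, LCP1 -1.39 and 1.54, and IL7R 0.82 and -1.33.

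Inflammatory genes went different ways with the siRNAs. Of 22 measured NF-kB and cytokine genes, 12 were at least 1.5-fold higher with siAURKA-2 and 0 lower, with a median of 0.71 (percentile 100), while with siAURKA-1 8 were at least 1.5-fold lower and 0 higher, with a median of -0.05 (percentile 32.8). The neutrophil chemokine gene CXCL2 gave -0.95 with siAURKA-1 and 1.71 with siAURKA-2, IL1A gave -2.48 and 0.70, CCL20 gave -2.30 and 0.80, and CXCL8 gave -1.38 and 0.83. IL6 and RELB, encoding an NF-kB subunit, were higher with siAURKA-2 (1.09 and 1.20). In all, 7 members were at least 1.5-fold lower with siAURKA-1 and at least 1.5-fold higher with siAURKA-2. Relative to DMSO these 7 stayed above it with siAURKA-2, by 1.15 for IL1A to 2.34 for IL24, whereas with siAURKA-1 TNFAIP3 was 0.52 above DMSO and IL24 (-0.05) and CXCL8 (-0.24) were closer to it than to siNT.

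Other groups differed with siAURKA-1 in particular genes. Of 24 immediate early genes, many of which respond within minutes to mitogens, 5 were at least 2-fold lower with siAURKA-1 and the median was -0.21 (percentile 2.39). FOSL1 (-1.22), KLF4 (-1.19), CCN1 (-1.18) and CCN2 (-1.16) were examples, while EGR1 was higher (1.07) but -0.40 below DMSO, since siNT lay far below DMSO for it (-1.47). Against DMSO the median was -0.09 (percentile 5.90), within the random lists, with KLF4 at -0.16 and CCN2 at -0.20. The median with siAURKA-2 was 0.04. In the unfolded protein and integrated stress response list the medians were -0.05 and 0.00, within the random lists. Yet ASNS, the asparagine synthetase gene (-2.08), PSAT1 of serine synthesis (-1.61) and the transcription factor gene ATF4 that regulates both (-1.22) were lower with siAURKA-1. With siAURKA-2 the endoplasmic reticulum stress genes DDIT3 (0.98), HERPUD1 (0.94) and HSPA5 (0.68) were higher. Keratinocyte differentiation genes had a median of 0.04 with siAURKA-1 (percentile 98.4), where the epithelial transcription factor genes GRHL3 (1.36) and ELF3 (1.14) and the calprotectin gene S100A9 (1.15) were at least 2-fold higher, and 0.02 with siAURKA-2, where the protease gene KLK5 was lower (-1.17). Against DMSO the former median was 0.00 (percentile 32.2). Mesenchymal genes had a median of -0.05 with siAURKA-1 and -0.25 with siAURKA-2 (percentile 0.30), the latter with TNC at -1.23 and SPARC at -0.84. Against DMSO that median was -0.03 and TNC was -0.61, since the siNT array lay above DMSO for this list (0.23, percentile 99.9). Basal squamous epithelial genes had medians of 0.04 and -0.21 (percentile 2.37 with siAURKA-2), the latter -0.13 against DMSO (percentile 4.41).

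**Figure D3:**
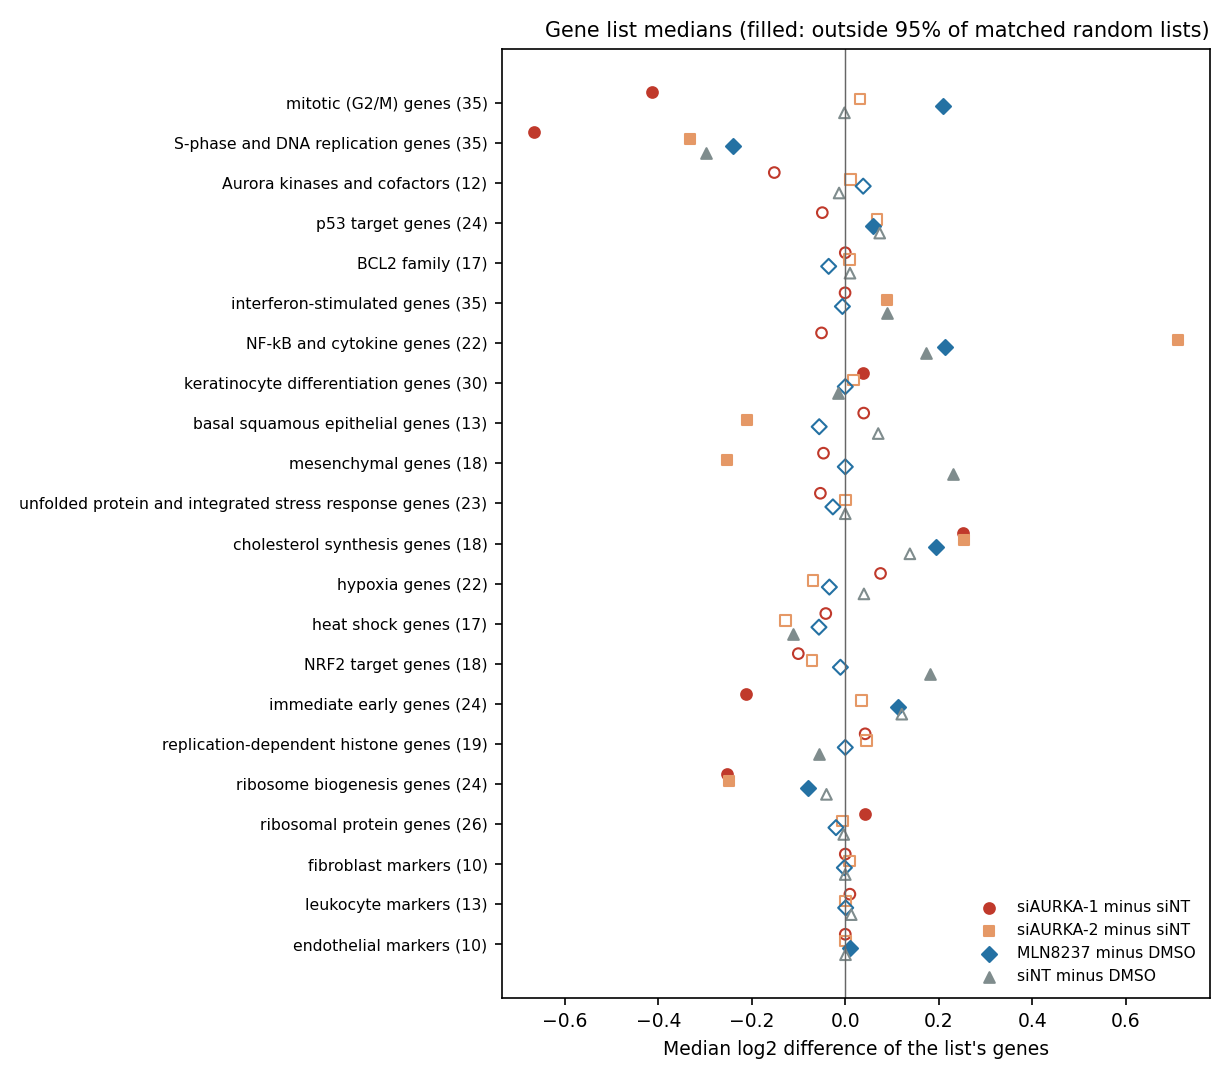
Median log2 difference of each gene list (rows, measured genes in brackets) in the 4 comparisons (symbols and colours). Filled symbols lie outside the middle 95% of 10000 random lists of the same size matched on spread over the arrays, as for S-phase genes in all 4 comparisons (-0.67, -0.33, -0.24 and -0.30).

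Kinase inhibition was compared with vehicle. MLN8237 gave few genes past 2-fold: 10 were higher and 2 lower than with DMSO, which is fewer than the 54 that differed between the 2 controls. The direction depends on the control, with 16 higher and 24 lower against siNT, and 2 higher and 6 lower against the mean of both. The largest values were those of VIM (1.83), TNFAIP3, an inhibitor of NF-kB signalling (1.54), HSD11B1, which regenerates cortisol (1.25), ANKRD1 (1.24) and CXCL8 (1.20). RNF182 (1.05), ZBED2 (1.04), CXorf58 (1.04), HMGCS1 (1.02) and TMEM156 (1.01) completed the 10, and the tubulin gene TUBA1A (0.998) and the neurofilament gene NEFL (0.996) lay just short of 2-fold. IGFBP3, an insulin-like growth factor binding protein (-1.58), and the annexin gene ANXA10 (-1.18) were at least 2-fold lower. Next were OTUD1, a deubiquitinase gene (-0.99), DIO2, the type 2 iodothyronine deiodinase (-0.98), the cadherin-family gene FAT2 (-0.94), ID1, an inhibitor of basic helix-loop-helix factors (-0.84), NNMT (-0.82) and OLR1 (-0.80).

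Many of these genes differed from DMSO in the same direction on the siNT array, which received no inhibitor. VIM was higher there by 1.74, HSD11B1 by 1.81, ANKRD1 by 1.55, CXCL8 by 1.14 and TNFAIP3 by 1.11, and IGFBP3 was lower (-0.78). Set against siNT instead of DMSO, MLN8237 gave 0.09 for VIM, -0.56 for HSD11B1, -0.30 for ANKRD1, 0.06 for CXCL8, -0.54 for CXorf58, -0.28 for ZBED2 and -0.14 for TMEM156. HMGCS1 was then at 0.59, IGFBP3 at -0.80 and OLR1 at -0.77, all short of 2-fold, and DIO2 at -1.04. ANXA10 was higher with siNT than with DMSO (1.32), and so lay at -2.50 when MLN8237 was set against siNT. The control probe sets also set the DMSO array apart: the polyadenylated spike-in transcripts had a median of -0.50 there, against -0.10 with MLN8237, 0.00 with siNT, 0.17 with siAURKA-1 and 0.15 with siAURKA-2. The MLN8237 and siNT differences from DMSO, which share that array, had an r of 0.455 across genes, against 0.50 in simulated unchanged groups of equal spread sharing 1 control array.

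Mitotic genes were slightly higher with MLN8237. Their median was 0.21 (percentile 100) and no member reached 1.5-fold, with the kinetochore motor gene CENPE (0.58), the cytokinesis kinesin gene KIF20A (0.54) and NDC80 of the outer kinetochore (0.46) at the top. The value was 0.20 against siNT as well. CCNB1 gave 0.22 and MKI67 0.08, the latter with 3 of 6 probe sets in that direction. S-phase genes had a median of -0.24 (percentile 0), for example POLE2 (-0.55) and PRIM1, a primase subunit (-0.51), but 0.03 against siNT (percentile 98.6). Cholesterol synthesis genes had a median of 0.19 (percentile 100), with IDI1 (0.66) and MSMO1 (0.65) after HMGCS1, and 0.05 against siNT (percentile 97.7). NF-kB and cytokine genes had a median of 0.21 (percentile 100), with 7 members at least 1.5-fold higher, and -0.01 against siNT (percentile 74.6). Immediate early genes gave 0.11 (percentile 99.95) and p53 targets 0.06 (percentile 98.3), with CDKN1A at 0.12 and MDM2 at 0.13. Against siNT these medians were 0.01 and 0.00. Ribosome biogenesis genes gave -0.08 (percentile 0.45), with PES1 at -0.30, and -0.02 against siNT.

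Knockdown and inhibition were then set side by side, since both aim at the same kinase. No gene (0 of 18239) was at least 2-fold different in the same direction with both siRNAs and MLN8237. Independent lists would share only 0.059 higher and 0.028 lower genes between siAURKA-1 alone and MLN8237. A count of 0 is therefore what unrelated lists would give too, and it carries little information. At 1.5-fold, 4 genes were shared by all 3. Those at the head of the ranking were FUCA1, a lysosomal fucosidase gene (0.84 with siAURKA-1, 1.11 with siAURKA-2 and 0.84 with MLN8237), and HMGCS1 (0.93, 0.80 and 1.02). BCLAF3 (0.89, 0.58 and 0.66) and the oxytocin receptor gene OXTR (0.84, 0.91 and 0.55) followed. In the lower direction, ANXA10 (-0.92, -1.85 and -1.18) and NNMT, nicotinamide N-methyltransferase (-1.56, -0.94 and -0.82), led, although against DMSO ANXA10 was 0.40 with siAURKA-1 and NNMT -0.01 with siAURKA-2. The replication genes ORC1 (-0.72, -0.53 and -0.59) and PRIM1 (-1.20, -0.73 and -0.51) and the histone chaperone gene NASP (-0.49, -0.51 and -0.57) came next. With MLN8237 against siNT these 3 genes kept their sign at smaller size (-0.18, -0.23 and -0.33).

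Other genes went opposite ways. GDF15 (1.52, 2.21 and -0.51), ST6GALNAC2 (1.26, 1.39 and -0.49), OTUD1 (1.73, 0.82 and -0.99) and ID1 (0.73, 1.07 and -0.84) were higher with the siRNAs and lower with MLN8237. RNF182 (-1.32, -1.04 and 1.05), the tubulin gene TUBB2A (-1.01, -1.13 and 0.93) and PMEPA1 (-0.95, -2.19 and 0.74) were lower with the siRNAs and higher with MLN8237. Several of these signs turn with the control array. PMEPA1 was 0.55 above DMSO with siAURKA-1 and -0.76 below siNT with MLN8237. GDF15 and ID1 were 0.15 and 0.19 above siNT with MLN8237, and ID1 with siAURKA-1 (-0.31) and OTUD1 with siAURKA-2 (-0.03) lay below DMSO. RNF182 and TUBB2A kept their signs at smaller size. Against DMSO they were -0.67 and -0.39 (RNF182) and -0.30 and -0.42 (TUBB2A), and with MLN8237 against siNT 0.40 and 0.22. ST6GALNAC2 kept its signs at slightly larger size, at 1.39 and 1.52 against DMSO and -0.62 with MLN8237 against siNT. At 1.5-fold, 31 genes were lower with siAURKA-1 and higher with MLN8237 and 4 the reverse, while 9 were higher and 4 lower with both. For siAURKA-2 the corresponding numbers were 13, 4, 13 and 3. Independent lists would share 1.72 higher and 0.94 lower genes for siAURKA-1 and MLN8237, and 1.32 and 0.65 for siAURKA-2. The number expected in opposite directions was not computed. Across genes the mean siRNA difference and the MLN8237 difference had an r of -0.01 and a rho of 0.03. With a common control r was 0.365 (DMSO) or 0.462 (siNT), with covariances of 0.0113 and 0.0202. Sharing the control array gave 0.577 and 0.0191 in simulated unchanged groups of equal spread, so the common-control values cannot be read as agreement.

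The 2 control arrays gave the background for these counts. Between siNT and DMSO, which differ in treatment, 54 genes were at least 2-fold apart (42 higher with siNT, 12 lower). Higher genes were TMPRSS11E (2.34), HSD11B1 (1.81), the interferon-inducible GTPase gene GBP1 (1.76), VIM (1.74) and PKIB (1.69). Lower genes were RAB40B (-1.89), the immediate early transcription factor gene EGR1 (-1.47), the mitochondrial magnesium channel gene MRS2 (-1.42), MYL12B (-1.28) and C2orf15 (-1.15). The cytokine gene IL24 was higher with siNT (1.62), as was INSIG1, a regulator of sterol sensing (1.11). NF-kB and cytokine genes had a median of 0.17 (percentile 99.3) and cholesterol synthesis genes 0.14 (percentile 96.0). Fibroblast, leukocyte and endothelial marker genes had medians of 0.00 or 0.01 in this and in the treatment comparisons, and no such gene was at least 1.5-fold different in any of them.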

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

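The tests of the 3 patterns weighed first in this part were chosen after the results had been seen, although siNT as the control of MLN8237 had been planned. The bound for the genes shared by the siRNAs, the highest count in simulated unchanged groups, replaced a bound of 1 in 4 genes after the count of 3 had been seen.

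Of the genes at least 2-fold different with both siRNAs, 15 were higher and 35 lower than on the siNT array, which both comparisons share. Of these, 3 of the 15 and 4 of the 35 were also at least 2-fold beyond both the DMSO and the MLN8237 array. The maximum was 0 in simulated unchanged groups, or 1 and 2 with deviations drawn among genes of like spread. AURKA, 1 of the 4, is the siRNA target, so its place among them was fixed in advance and lends no weight. The others were DTL, APLN and FABP5, close to that maximum of 2. Readings of the siNT array alone may thus leave a few genes unaccounted for, by a small margin. The simulated arrays all had the same spread, whereas the genes' standard deviation was 0.26 and 0.21 on the siRNA arrays and 0.14 on siNT. The bound thus leaves out any larger sample-to-sample variation of the siRNA arrays. An effect of the siRNAs alone leaves another part unaccounted for, since 5 of the 15 (C2orf15, GLRB, MYL12B, PI4K2A and ZNF428) were low on the siNT array while both siRNA arrays lay within 1.5-fold of the mean of DMSO and MLN8237, and 3 of the 35 (ALOX5AP, ANGPTL4 and CHML) were high on it by the same measure. Such genes may reflect the siNT sample, and more lean on it by a looser measure, as siNT lay at least 1.5-fold the other way from DMSO for 8 of the 15 and 15 of the 35. For the remaining genes an effect of lowered AURKA stays open as untested by replicates.

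Of 22 measured cytokine genes, 7 were at least 1.5-fold lower with siAURKA-1 and at least 1.5-fold higher with siAURKA-2 than with siNT. A deeper knockdown by siAURKA-1 of the same response would not by itself give opposite directions, yet it stays open, because only 3 of the 22 (IL1A, IL1B and CCL20) were that far apart from DMSO as well and these counts restate the pattern. More degraded RNA in 1 of the siRNA samples is argued against by the 3' minus 5' values of GAPDH and ACTB, which differed between these arrays by at most 0.0463 (log2). An effect of 1 siRNA on transcripts other than AURKA may contribute to the 394 genes at least 2-fold apart between the siRNA arrays, but it cannot be told apart from other differences between the samples, since the siRNA sequences were not used here and each siRNA has 1 array.

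S-phase genes were lower in all treatments relative to their planned controls. For MLN8237, high readings of these genes on the DMSO array are a candidate explanation, because the list's median became 0.0325 (log2) when MLN8237 was set against siNT. For the siRNAs that explanation does not apply by design, because their planned control was siNT and the DMSO array does not enter. The higher of their medians against siNT was -0.33, with siAURKA-2. It lay at percentile 2.10, or at 3.8 and so within the random lists with the widest-ranging probe set per gene. What made the DMSO array differ, a lower spike-in signal included, stays open. The 3' minus 5' value of ACTB also differed between the controls, at -0.11 with DMSO and 0.14 with siNT. That of GAPDH was 0.03 and 0.02. An effect of lowered AURKA on replication genes stays open as a hypothesis for the siRNAs.

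The mitotic gene median was -0.41 with siAURKA-1 and 0.21 with MLN8237, in opposite directions, a difference that was not tested. Immediate early genes likewise had a median of -0.21 with siAURKA-1 and 0.11 with MLN8237, also not tested. Outside the gene measurements, the polyadenylated spike-in transcripts had medians of 0.17 on the siAURKA-1 array and 0.15 on the siAURKA-2 array, above both controls (-0.50 with DMSO and 0.00 with siNT). Among 4040 probe sets without a single named gene, 15 were at least 2-fold different in the same direction with both siRNAs (5 higher, 10 lower).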

How the results depend on the processing

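The probe set, suffix, mean-centring, mean-of-controls and probe-number settings, and the other control for named genes, were chosen after seeing the data, and the rest had been planned. No paired analysis was possible because each group has 1 array and no replicate numbers link the groups. The AURKA difference stayed between -3.51 and -3.35 for siAURKA-1 and between -2.79 and -2.63 for siAURKA-2 in the 6 alternatives run, and between 0.49 and 0.64 for MLN8237. Centring each array on its median moved none of the counts, medians or correlations, because array medians were already 0.

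With the widest-ranging probe set per gene, counts were 762 (siAURKA-1), 559 (siAURKA-2), 32 (MLN8237), 180 (siNT minus DMSO) and 119 (both siRNAs), larger by construction since that choice favours extreme probe sets, and 5 lists lay outside the random lists for siNT minus DMSO (8 in the report). The lists no longer outside were S-phase and mesenchymal (siAURKA-2), keratinocyte and immediate early (siAURKA-1), p53 and endothelial (MLN8237) and cytokine, keratinocyte and histone genes (siNT minus DMSO). Aurora (siAURKA-1), p53 (siAURKA-2) and ribosomal protein genes (MLN8237) were newly outside. Without s or x probe sets 4 lists (7 in the report) lay outside for siAURKA-1 and 4 (8) for siNT minus DMSO. No longer outside were keratinocyte, immediate early and ribosomal protein (siAURKA-1), interferon, basal and mesenchymal (siAURKA-2), ribosome biogenesis and endothelial (MLN8237) and interferon, cytokine, keratinocyte, heat shock and histone genes (siNT minus DMSO). Ribosomal protein (siAURKA-2), stress response (MLN8237) and hypoxia genes (siNT minus DMSO) were newly outside. With the mean of both controls, keratinocyte (siAURKA-1) and S-phase, p53, ribosome biogenesis and endothelial genes (MLN8237) were not outside. Hypoxia and heat shock (siAURKA-2) and interferon, stress response, NRF2 and histone genes (MLN8237) then became outside. Keratinocyte and ribosomal protein (siAURKA-1), keratinocyte (siNT minus DMSO) and endothelial genes (MLN8237) were not outside with either other kind of random list, nor were immediate early (siAURKA-1) and endothelial genes (MLN8237) with arrays centred on their mean. At 1.5-fold the counts were 1286, 926, 88, 380 and 281, with 4 genes for both siRNAs and MLN8237. At 3-fold they were 68, 31, 1, 9 and 3. Random lists without matching, or matched on the number of probe sets, left 11 lists outside for siAURKA-2 in either case. Newly outside in both cases were Aurora, stress response, hypoxia and NRF2 (siAURKA-1) and p53, hypoxia, heat shock and NRF2 genes (siAURKA-2). So were heat shock (MLN8237) and p53, cholesterol, immediate early and ribosome biogenesis genes (siNT minus DMSO). Matching on the number of probe sets also added basal genes (MLN8237).

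Control arrays mattered most for MLN8237. With siNT as its control, 40 genes were counted (16 higher, 24 lower), 7 with both siRNAs as well, and the correlation with the mean siRNA difference was 0.462. With DMSO for the siRNAs these were 1 gene and 0.365, and with the mean of both controls 0.230. Sharing the control gave 0.577, or 0.408 for the mean of both, in simulated unchanged groups of equal spread, so these correlations cannot be read as agreement. Genes counted with both siRNAs numbered 28 with the mean of both controls, and 26 and 19 when each siRNA had its own control, with correlations of 0.118 and 0.162. MLN8237 minus siNT reversed the medians of S-phase (0.0325) and NF-kB and cytokine genes (-0.00636). Signs of genes named by the rule were compared where the difference exceeded 0.195, the standard deviation of siNT minus DMSO over genes. Reversed with MLN8237 against siNT were HSD11B1 (-0.56), ANKRD1 (-0.30), ZBED2 (-0.28), CXorf58 (-0.54), TMEM156 (-0.14), TM4SF1 (-0.14), ZBTB20 (-0.21), TMPRSS11E (-1.82), PKIB (-1.04), ID1 (0.19), GDF15 (0.15), PMEPA1 (-0.76), NEDD9 (-0.16), BIK (-0.27), IL24 (-0.72), MCM6 (0.0756), LAMB3 (-0.10), MSMO1 (-0.24), INSIG1 (-0.55), HSPA1B (0.0705), BHLHE40 (-0.13), SPRY2 (-0.32), DUSP4 (-0.25), KLF4 (-0.56), KLK5 (0.0703), ELF3 (0.0855), SNAI2 (-0.11), DDB2 (0.0844) and PES1 (0.0811). Reversed against DMSO were, with siAURKA-1, PYGL (-0.11), TMPRSS11E (0.32), HSD11B1 (0.0871), GBP1 (0.58), PKIB (0.81), ID1 (-0.31), ALOX5AP (0.36), ANXA10 (0.40), EGR1 (-0.40), PMEPA1 (0.55), BIK (0.22), BCL2L2 (-0.12), COL6A3 (0.00326), HSPE1 (-0.26) and ISG20 (0.18), and, with siAURKA-2, TMPRSS11E (0.88), OTUD1 (-0.0288), FAT2 (-0.11), ANGPTL4 (0.0362), SOWAHC (0.15), EGR1 (-0.91), ANKRD1 (1.08), CXorf58 (0.60), TMEM156 (0.35), BCL2L2 (-0.12), AKR1B10 (0.12) and CCN2 (0.18). The cause of the control dependence was not tested for single genes. Filters at the 40th or 60th percentile, the highest-mean probe set, cyclic loess and matching on mean expression were not run, because centred values hold no levels, and AURKA has no other probe set. For the same reason signal over background is unknown for each gene.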

Other observations

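The tests of the augmin, YAP, TGF-beta and tubulin genes are given as chosen after the results had been seen, because the members left out of the last 3 lists, those in a fixed list or named elsewhere, and the bounds for an opposite direction were settled after the list values were known. THBS1 and TUBA4A, each at least 2-fold lower with both siRNAs than siNT, were left out as well.

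Histone genes had list medians near 0 with both siRNAs (0.04 with siAURKA-1 and 0.05 with siAURKA-2), but single members were far apart on the siAURKA-2 array. H2BC5 was 2.27 above siNT, H2AC6 2.11 and H2BC4 1.03, while H2BC9 was lower (-1.04). Against DMSO H2AC6 was 1.05, as siNT lay -1.07 below DMSO for it. With siAURKA-1 the largest member difference was that of H4C3 (-0.68). With MLN8237 the median was 0.00, but 0.09 against siNT (percentile 99.9), as siNT lay below DMSO (-0.06, percentile 2.28). Interferon-stimulated genes were slightly higher with siAURKA-2 (median 0.09, percentile 99.5), led by IFIT2 (1.42), IFI6 (0.62) and IFIT3 (0.62), against a median of 0.00 with siAURKA-1 and -0.01 with MLN8237. The siNT array lay above DMSO by the same median of 0.09, and with the other control siAURKA-1 was at 0.12 (percentile 99.1) and MLN8237 at -0.10 (percentile 0.52), so the contrast depends on the control.

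Hypoxia genes had medians of 0.08 with siAURKA-1, -0.07 with siAURKA-2 and -0.03 with MLN8237, all within the matched random lists. Without matching, the medians with siAURKA-1 (percentile 98.4) and siAURKA-2 (percentile 0.89) lay outside the random lists. VEGFA was lower with siAURKA-1 (-0.57), and LDHA, encoding lactate dehydrogenase A, with siAURKA-2 (-0.64). Heat shock genes gave -0.04, -0.13 and -0.06, also within the random lists, but against DMSO -0.25 with siAURKA-1 (percentile 0.25) and -0.29 with siAURKA-2 (percentile 0.03), as siNT lay below DMSO (-0.11, percentile 0.54), with HSP90AA1 lower with both siRNAs (-0.46 and -0.49). Among NRF2 targets (medians -0.10, -0.07 and -0.01), the cystine transporter gene SLC7A11 was lower with siAURKA-1 (-1.62), NQO1 was lower with siAURKA-2 (-0.94), and GCLM of glutathione synthesis was lower with both (-0.76 and -0.76). For this list MLN8237 was at -0.25 against siNT (percentile 0.02), as siNT lay above DMSO (0.18, percentile 99.7).

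As ANKRD1 and VIM were far lower with siAURKA-1, lower YAP target gene levels were proposed as a hypothesis. The 17 YAP target genes in no fixed list and not named had a median of -0.19 with siAURKA-1, at percentile 5.90, which did not pass the bound of 2.5, and 7 of them were at least 1.5-fold lower. Against DMSO the 17 had a median of 0.00 (percentile 39.2) with 2 at least 1.5-fold lower, and siNT lay 0.19 above DMSO for them (percentile 98.9). All 22 members had a median of -0.20 against siNT (percentile 9.74), so the hypothesis stays undecided. TGF-beta target genes were examined because PMEPA1, THBS1, ADAMTS1 and ANGPTL4 were lower with both siRNAs. The 14 members in no fixed list and not named had medians of -0.07 with either siRNA, the higher percentile being 31.87, and all 21 had medians of -0.21 and -0.16 (percentiles 14.2 and 10.2). This leaves the hypothesis undecided. The 14 were higher with siNT than with DMSO (0.38, percentile 100), and against DMSO their medians were 0.11 and 0.17 (percentiles 85.6 and 95.1). Tubulin genes were examined because TUBA1A and TUBB2A were higher with MLN8237. TUBA1A, TUBB2A and TUBA4A (0.25 with MLN8237) were left out. The other 15 members had a median of 0.02 at percentile 90.28, short of the upper bound of the random lists. This also leaves that hypothesis undecided. With siAURKA-1 all 18 had a median of -0.53 against siNT (percentile 0.01), with 7 at least 1.5-fold lower, and -0.34 against DMSO (percentile 0.03). The 15 gave 0.00 against siNT (percentile 52.1) and -0.19 against DMSO (percentile 0.57), and with siAURKA-2 -0.04 (percentile 21.2) and -0.15 (percentile 0.725). With siAURKA-1, 4 of the 15 were still at least 1.5-fold lower than siNT, TUBB (-0.96) most, and 0 higher. The median of 0.00 falls on TUBB4A, which was level in every comparison.

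Augmin subunits, which recruit gamma-tubulin to spindle microtubules, were lower with siAURKA-1. The 8 subunits had a median of -0.68 (percentile 0.23) and 6 of them were at least 1.5-fold lower, HAUS8 (-1.62), HAUS1 (-1.07) and HAUS2 (-0.95) most. With siAURKA-2 the median was -0.32, and the highest of the percentiles over both siRNAs and both controls was 6.56, so a lower level with both siRNAs remains undecided.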
